A study of Mus musculus with 15 samples.

How the data were processed

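Total RNA libraries were sequenced from skin of female SKH1 mice. RNA was isolated with an RNeasy kit and libraries were made with a TruSeq Stranded Total RNA kit, per the labels' protocols. Reads were trimmed with Trim Galore, placed on the mouse build GRCm38 (mm10) and tested with DESeq2, per the submitters' processing notes. The aligner, the counter, the annotation, versions and the design formula are not given in the sources used here. The authors deposited 4 tables of gene symbols, each for 1 comparison. Per the file headers each holds a log2 fold change, in the unit of the authors' model. Each also holds a Wald statistic, a score that is the fold change over its SE, as deposited by the authors. The p-value and adjusted p-value in them are those of the authors' DESeq2 Wald test with Benjamini-Hochberg adjustment, per the file headers and the processing notes. There are no counts, means or values per library in these tables, and 0 columns of per-library values went unused. The depth of each library is therefore unknown, and no interval that needs counts is given. The precision of a fold change is given by its SE, computed as the log2 fold change over the Wald statistic.

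The tables list 24027 symbols in common after 25 symbols that a spreadsheet had turned into dates were removed. Of these 5199 have no fold change in any table. The p-values equal the normal tail of the Wald statistic, with a largest difference of 9.9e-13 in the natural log of p. An adjusted p is missing where the authors' filter on low counts removed a gene, and such genes were not tested. This left 14124, 15201, 15201 and 10899 genes. Coordinates come from GENCODE mouse release 21 on GRCm38, in which 22683 symbols (94.4%) match 1 annotated gene.

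The direction and identity of each table were taken from its header and checked on genes without reads. A fold change and Wald statistic of exactly 0 were taken to mark genes without reads in both groups. One table is named for perilesional and lesional skin, while its header names lesional and back skin of placebo mice. Of the 1423 genes at 0 in non-lesional over non-UV skin, 704 are positive and 0 negative in that table. Of the 1195 at 0 in perilesional over non-lesional skin, 271 are negative in it, which could not occur if its reference were perilesional skin. It was therefore used as lesional over back skin. Back is taken as the non-UV-exposed group by elimination, since the other 4 groups have names of their own in the headers. Among 2235 genes flat in every table the median SE relative to that table was 1.004, 0.986 and 1.001, so 1 fit over all libraries was assumed. Lesional over perilesional skin was then derived as the deposited log2 fold change of lesional over non-UV skin minus those of the 2 steps before it. Its variance was the squared SE of lesional over non-UV skin minus that of non-lesional over non-UV skin plus that of perilesional over non-lesional skin, which is exact when the model holds the group alone, a point the labels do not state. Its p-values are normal tails with Benjamini-Hochberg adjustment over 15187 genes. The table of placebo over GZ21T lesions was turned in sign. A planned check of direction from mean counts could not be run, and the comparison of lesional with non-UV skin was added. GZ21T lesional over placebo non-lesional skin was derived in the same way.

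Gene lists were tested with limma's cameraPR on the Wald statistic, two-sided, with a preset correlation of 0.01. Benjamini-Hochberg adjustment ran over all lists and the 4 planned comparisons together, and over the added comparison of lesional with non-UV skin by itself. The 40 lists were fixed before the data were examined, and 39 could be tested, since the mitochondrially encoded list has 0 members in the tables. In GZ21T over placebo lesions 36 could be tested. There the B and plasma cell, mast cell and eosinophil, and melanocyte lists kept too few members with an adjusted p. An estimated correlation needs values per library, so preset correlations of 0.05 and 0.1 were run instead. Counts of changed members use adjusted p under 0.05 over all genes tested, and again adjusted over the list alone. Another 8 lists, written after the tables were seen, were tested in the same way, adjusted apart from the 40, and are given in the closing section. Named genes followed a rule set beforehand. It takes the 8 largest and 8 smallest fold changes among called genes with a proper symbol, up to 4 members with the smallest adjusted p of each list described, 11 fixed genes found in the tables, and the called genes with opposite signs in lesions and under GZ21T. The rule asked for a minimum mean count. As the tables hold none, an adjusted p in every table stood in for it, a choice made after the tables were seen. Log2 fold changes over 15 in size arise where a group has no reads and are not given as sizes. Of the genes tested everywhere 15, in 6 groups, have values identical to another gene in all tables and are uncertain through shared reads, as are Hbb-b2 and Hbb-bt, which were not tested everywhere. Filaggrin, mitochondrial, T cell receptor and immunoglobulin constant genes are not analysed here, and the values of some single genes that the rule names are not reported here.

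Correlations of fold changes across genes were set beside 100 simulations of unchanged groups, drawn from the SEs with an equal part of each variance shared through the common libraries, and calls in common beside the number that independent lists would give. Simulated ranges of r run between outer percentiles of the 100 simulations and are not their extremes. The scripts were tested on simulated data with 200 changed genes in each of 20 runs on 10898 genes. For lesional over perilesional skin 59.6% of genes changed by a log2 fold change of 1 were recovered, 90.1% at 2 and 97.8% at 4, and 5.8% of calls were unchanged genes. For lesional over non-UV skin the values were 58.1%, 90.1%, 97.8% and 4.6%, and for GZ21T over placebo lesions 61.4%, 90.5%, 97.4% and 5.1%. Of shifted lists 98.5% and of unshifted lists 1.17% were called, on independent random values given to the genes of GZ21T over placebo lesions. The gene simulations drew normal noise, independent between genes, from the SEs that the test itself uses. All these rates check the scripts and are not error rates for the real data, where genes may be correlated. Alternatives covered the threshold, a minimum fold, the genes adjusted over, a null spread estimated from the genes by median and MAD, centring on the median, list correlation, ranks, overlapping lists, Fisher's exact test, transcript length, and the part of variance shared in simulations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.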

Results

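RNA-seq was carried out on skin of female SKH1 mice, a hairless strain used for ultraviolet carcinogenesis. Mice aged 6 to 8 weeks were irradiated with 500 J/m2 of ultraviolet B on 5 days per week for 10 weeks, which gives actinic keratoses, the keratinocyte lesions that precede squamous cell carcinoma. A placebo cream or a cream with GZ21T, 0.25 g on 5 days per week, was applied. The labels define 5 groups of 3 libraries, 15 in all. Of the placebo mice there is lesional, perilesional, non-lesional and non-UV-exposed skin, and of the GZ21T mice there is lesional skin. The labels number the libraries of each group 1 to 3, and those of the 4 placebo groups read Control 1 to 3 at every site. The placebo sites may thus come from the same mice, a pairing that could not be used here. The labels do not state outright that each number is a separate animal, so p-values measure the spread between these libraries, which may in part be technical. The deposited tables hold fold changes and test results for 4 comparisons and no values per library, so the depth of each library is unknown and no statement can be made on how many libraries show a change. Among genes tested in every table the median standard error (SE) of a log2 fold change lay between 0.27 and 0.28.

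Skin that was irradiated but free of lesions was compared first with skin that was not exposed. The headers call the unexposed group back skin, so a difference of body site may accompany that of ultraviolet exposure. These cannot be told apart in this comparison. By the authors' deposited table, 235 of 14124 genes changed, 160 higher and 75 lower in non-lesional skin, with a median absolute log2 fold change of 1.68 among them. Keratins of wounded and hyperproliferative epidermis were among the genes that rose: the authors' deposited table gives Krt6b a log2 fold change of 5.10 ± 0.78 (SE; adjusted p = 8.6e-08) and Krt16 one of 3.70 ± 0.45 (adjusted p = 1.3e-12). Chil4, a chitinase-like protein of type 2 inflammation, was 8.59 ± 1.5 higher (adjusted p = 8.3e-06) in the authors' deposited table, and the cornified cell protein repetin, Rptn, was 4.49 ± 0.44 higher (adjusted p = 4.3e-20). Interferon-induced genes rose together, with 13 of 37 members higher, none lower, and 22 higher when adjusted over the list alone (list adjusted p = 1.1e-33). Among them the chemokine gene Cxcl9 rose by 3.21 ± 0.46 (adjusted p = 3.5e-09) in the authors' deposited table. Chil4 lies at chromosome 3, 106201490 to 106219507, minus strand, of GRCm38.

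Of the stress keratin and alarmin genes 8 of 18 were higher and none lower, and 10 were higher and 1 lower adjusted over the list alone (list adjusted p = 7.8e-21). Of the 37 cornified envelope genes, whose products build the outer barrier of the epidermis, 9 were higher and none lower, and 18 were higher and 1 lower adjusted over the list alone (list adjusted p = 7.1e-19). They include the desmosomal cadherin Dsc1 at 1.61 ± 0.28 (adjusted p = 4.5e-06) and Lce1h, a late cornified envelope gene, at 1.55 ± 0.34 (adjusted p = 0.0011) in the authors' deposited table. Sprr2a1 and Sprr2a2 carry identical values of 4.57 ± 0.83 (adjusted p = 2.5e-05) in the authors' deposited table, so reads shared between these near-identical genes leave each of them uncertain. Also higher in the authors' deposited table were the cysteine protease inhibitor Stfa2 at 4.90 ± 1.3 (adjusted p = 0.016) and the guidance ligand Slit1 at 3.44 ± 0.93 (adjusted p = 0.021). T and NK cell genes were higher for 4 of 21 members and 5 higher and 2 lower adjusted over the list alone (list adjusted p = 0.004, and 0.12 as the adjusted p with a correlation of 0.1). Icos, a costimulatory receptor of T cells, stood at 2.86 ± 0.57 (adjusted p = 0.00021), Cd8a at 2.94 ± 0.69 (adjusted p = 0.0037) and Cd3e at -1.20 ± 0.44 (adjusted p = 0.17) in the authors' deposited table.

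Macrophage genes fell in the same comparison, with 3 of 25 lower and 1 higher, and 9 lower and 2 higher adjusted over the list alone (list adjusted p = 3.8e-05). In the authors' deposited table the lipid receptor Trem2 stood at -3.19 ± 0.78 (adjusted p = 0.0056), the lysosomal protein Cd68 at -2.23 ± 0.57 (adjusted p = 0.01) and the macrophage elastase Mmp12 at -4.04 ± 0.96 (adjusted p = 0.004). The beta-glucan receptor Clec7a stood at -3.97 ± 0.78 (adjusted p = 0.00016) there, and the transcription factors Fosb and Atf3 at -3.98 ± 0.90 (adjusted p = 0.0022) and -3.21 ± 0.61 (adjusted p = 5.9e-05) in the authors' deposited table. The stem cell keratin Krt15 stood at -2.0 ± 0.46 (adjusted p = 0.003) in the authors' deposited table and was the member of the basal keratinocyte list that changed, 1 lower of 16 over all genes and adjusted over the list alone (list adjusted p = 0.014, and 0.062 as the adjusted p with a correlation of 0.05). Further lists of cell types and matrix had negative medians. Collagen genes had a median of -0.81 (list adjusted p = 0.0021, and 0.14 as the adjusted p with a correlation of 0.1) and adipocyte genes one of -1.08 (list adjusted p = 0.021, and 0.087 with 0.05), with 0 of 30 and 0 of 18 changed over all genes and 0 adjusted over the list alone. Neutrophil genes had a median of -1.73, with 1 of 12 higher and 1 lower, and 1 higher and 6 lower adjusted over the list alone (list adjusted p = 0.01, and 0.12 as the adjusted p with a correlation of 0.1). On the genes with an adjusted p in every table that call ended and its direction turned (adjusted p = 0.43). The haemoglobin gene Hba-a2 was called lower, but a group without reads sets its fitted value, so no size is given. Mki67, a proliferation marker, stood at 0.43 ± 0.29 (adjusted p = 0.71) in the authors' deposited table, while the cell cycle list as a whole was shifted upward with 0 of 32 members changed over all genes and 0 adjusted over the list alone (list adjusted p = 4.2e-06). Markers of other tissues moved as well: the hair list shifted down by a median of -1.98 (list adjusted p = 1.1e-08) and the skeletal muscle list up by 1.65 (list adjusted p = 2.5e-05), with 0 of 34 and 0 of 29 members changed and 0 adjusted over the list alone in each. Genes of body position moved too, in lists written after the tables were seen: 1 of 16 HoxA and HoxB genes was higher, and 8 adjusted over the list alone (list adjusted p = 9.6e-08), while HoxC genes had 0 of 7 changed over all genes and 0 adjusted over the list alone with a median of -0.73 (list adjusted p = 0.007). In all, 19 of 39 lists were called, of which 16 held with a preset correlation of 0.05 and 10 with 0.1. With the null spread taken from the genes themselves 139 genes remained called.

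Perilesional skin was then compared with non-lesional skin, both irradiated, to ask what distinguishes the skin around a lesion. Genes of the sebaceous gland and of fatty acid synthesis rose. Of 15201 genes in the authors' deposited table, 17 changed, 14 higher and 3 lower. The fatty acid hydroxylase Fa2h was 4.75 ± 1.06 higher on the log2 scale (adjusted p = 0.018) and the elongases Elovl3 and Elovl6 were 3.52 ± 0.83 (adjusted p = 0.03) and 3.06 ± 0.60 (adjusted p = 0.0061) higher in the authors' deposited table. The ceramide synthase Cers4 was 2.80 ± 0.66 higher (adjusted p = 0.03) and the mitochondrial citrate carrier Slc25a1 1.45 ± 0.34 higher (adjusted p = 0.03) in the authors' deposited table. Of the 31 sebaceous and lipid synthesis genes 4 were higher and none lower, and 13 were higher and 1 lower adjusted over the list alone (list adjusted p = 2e-16). Fa2h lies at chromosome 8, 111345135 to 111393824, minus strand, of GRCm38.

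Hair follicle genes went the other way, with a median of -3.78 (list adjusted p = 2.8e-18): 1 of 38 was lower, and 21 were lower and 1 higher adjusted over the list alone. Trichohyalin, Tchh, a protein of the inner root sheath, stood at -3.66 ± 0.88 (adjusted p = 0.032) in the authors' deposited table, and Dsg4, a desmosomal cadherin of the hair cortex, at -4.84 ± 1.29 (adjusted p = 0.099). Lists of matrix and immune cells shifted upward with no member changed over all genes. Matrix proteases had a median of 1.16 (list adjusted p = 4.6e-07, 4 of 22 higher adjusted over the list alone), collagens one of 1.13 (list adjusted p = 6.4e-06, 0 of 30 adjusted over the list alone) and neutrophil genes one of 1.51 (list adjusted p = 0.00016, 5 of 14 higher adjusted over the list alone, and 0.99 as the adjusted p on the genes with an adjusted p in every table). Macrophage genes had a median of 1.02 (list adjusted p = 5.9e-07, 0 of 26 adjusted over the list alone). Mmp12 stood at 3.01 ± 0.96 (adjusted p = 0.24), Trem2 at 2.09 ± 0.78 (adjusted p = 0.4) and Col1a1 at 2.48 ± 0.90 (adjusted p = 0.38) in the authors' deposited table, so none of these genes passed alone. Krt16, at -0.02 ± 0.45 (adjusted p = 1), and Krt6a, at 0.41 ± 0.51 (adjusted p = 0.92), showed no detectable difference between these sites in the authors' deposited table. Of 39 lists 20 were called, 16 with a correlation of 0.05 and 9 with 0.1. With the null spread taken from the genes 1 gene remained called, and centring on the median gave 15 higher and 1 lower. Collagen, neutrophil and macrophage genes, shifted upward here, had negative medians in non-lesional over non-UV skin. The same non-lesional libraries enter both comparisons with opposite sign, so low levels in that group alone could give both shifts. In lesional over non-UV skin, which leaves that group out, macrophage genes had a median of -0.22 (list adjusted p = 0.68). Collagen genes had one of 0.93 there (list adjusted p = 0.13). Neutrophil genes had one of 1.1, with 4 of 14 higher and 1 lower (list adjusted p = 0.14).

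Lesions were set against the perilesional skin of the same treatment arm by a contrast derived from 3 deposited tables, since no table held it directly. Cornified envelope genes fell as a list in lesions, led by Lce1 genes, while genes of inflammation and of the response to low oxygen rose. Of 15187 genes 81 changed, 47 higher and 34 lower. Ptgs2, which encodes the inducible cyclooxygenase, rose by 5.24 ± 1.01 (SE; adjusted p = 0.0011), and Tslp, an epithelial cytokine, rose by 4.0 ± 0.88 (adjusted p = 0.0039). The collagenase Mmp13 rose by 4.39 ± 1.16 (adjusted p = 0.038), the stromelysin Mmp3 by 3.02 ± 0.76 (adjusted p = 0.025) and the AP-1 factor Fosl1 by 3.48 ± 0.75 (adjusted p = 0.0035). Ptgs2 lies at chromosome 1, 150100031 to 150108227, plus strand, and Tslp at chromosome 18, 32815383 to 32819797, plus strand, of GRCm38.

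Of 37 cornified envelope genes 9 were lower and 1 higher in lesions than around them, and 20 were lower and 1 higher adjusted over the list alone (list adjusted p = 3.5e-20). Lce1h fell by 1.89 ± 0.33 (adjusted p = 0.00018), Lce1c by 1.94 ± 0.37 (adjusted p = 0.0011) and Lce1a1 by 1.67 ± 0.33 (adjusted p = 0.0014). The neighbouring Lce6a fell by 1.96 ± 0.47 (adjusted p = 0.015). Lce3 genes did not fall with them, and Lce3c and Lce3d, chosen after their values were seen, stood at 1.73 ± 1.15 (adjusted p = 0.635) and 2.53 ± 1.24 (adjusted p = 0.45). Glycolysis and hypoxia genes were higher for 4 of 25 members, and for 12 adjusted over the list alone, with none lower (list adjusted p = 1.2e-14). They were led by Egln3, an oxygen-sensing hydroxylase, at 1.92 ± 0.40 (adjusted p = 0.0022), Ndrg1 at 2.41 ± 0.55 (adjusted p = 0.006) and the growth factor of vessels Vegfa at 1.38 ± 0.38 (adjusted p = 0.045). Of 25 chemokine and cytokine genes 3 were higher, and 4 adjusted over the list alone (list adjusted p = 8.2e-06), among them the alarmin Il33 at 1.87 ± 0.50 (adjusted p = 0.039). Matrix proteases were higher for 2 of 22 members, and for 4 adjusted over the list alone (list adjusted p = 0.00053, and 0.065 as the adjusted p with a correlation of 0.1). Basal keratinocyte genes had a median of 0.68 (list adjusted p = 0.0005), with 0 of 16 changed over all genes and 4 higher adjusted over the list alone. DNA replication genes had a median of 0.57 (list adjusted p = 1.4e-06) with 0 of 30 changed over all genes and 0 adjusted over the list alone. T and NK cell genes shifted down by a median of -0.70 (list adjusted p = 1.8e-06, 0 of 25 adjusted over the list alone), and Cd163l1, a scavenger receptor gene, fell by 2.79 ± 0.72 (adjusted p = 0.031). The hair list had a median of 3.22 (list adjusted p = 9.2e-11) with 0 of 38 changed over all genes and 10 higher adjusted over the list alone. This mirrors its median of -3.78 in perilesional over non-lesional skin, where the same perilesional libraries enter with opposite sign. Low hair content of the perilesional samples could give both shifts, and in placebo lesional over non-lesional skin the list's median was -0.4. Markers of blood and vessels were also shifted. Red blood cell genes, a list written after the tables were seen, had a median of 4.68 (list adjusted p = 2.1e-05) with 0 of 5 changed over all genes and 5 higher adjusted over the list alone. Of these Hbb-b2 and Hbb-bt carry identical values and amount to 1 measurement, which the count and the list p take as more than 1. Endothelial genes had a median of 1.16 (list adjusted p = 0.0066, and 0.051 as the adjusted p with a correlation of 0.05) with 0 of 22 changed over all genes and 0 adjusted over the list alone. Of 39 lists 17 were called, 15 with a correlation of 0.05 and 11 with 0.1. The count of genes was 21, 2 higher and 19 lower, with the null spread taken from the genes, and 53 with the largest of the 3 deposited SEs. Centring on the median gave 35 higher and 49 lower, so the majority among called genes turned with a shift of the median of 0.059.

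The table that sets lesions against non-UV-exposed skin was not among the planned comparisons. Keratinocyte stress, proliferation, interferon, glycolysis and lipid synthesis genes rose, and WNT target genes fell. By the authors' deposited table, 2785 of 15201 genes changed, 1543 higher and 1242 lower. Genes of body position differed as well, in lists written after the tables were seen, so body site cannot be told apart from exposure and lesion here. HoxC genes were lower for 4 of 7, and for 5 adjusted over the list alone (list adjusted p = 0.0039, and 0.026 with a correlation of 0.1). HoxA and HoxB genes were higher for 4 of 17, over all genes and adjusted over the list alone (list adjusted p = 0.041, and 0.11 as the adjusted p with a correlation of 0.05). Of 19 stress keratin and alarmin genes 14 were higher and 1 lower, and 16 higher and 1 lower adjusted over the list alone (list adjusted p = 2e-17). In the authors' deposited table Krt6b reached 6.60 ± 0.78 (adjusted p = 7.2e-14) and Krt16 4.15 ± 0.45 (adjusted p = 1.7e-16), whereas Krt77, an epidermal keratin, stood at -7.49 ± 1.10 (adjusted p = 5.5e-09). Of 32 cell cycle genes 21 were higher, and 25 adjusted over the list alone, with none lower (list adjusted p = 1.6e-09). The authors' deposited table gives Birc5, which encodes survivin, 1.70 ± 0.38 (adjusted p = 0.00032), and Mki67 0.52 ± 0.29 (adjusted p = 0.19). Interferon genes were higher for 26 of 37 members, and for 29 adjusted over the list alone, with none lower (list adjusted p = 1.3e-17). Glycolysis and hypoxia genes were higher for 19 of 25, and for 20 adjusted over the list alone (list adjusted p = 1.4e-14), with the glycolytic enzyme Eno1 at 2.06 ± 0.36 (adjusted p = 2.3e-06) in the authors' deposited table. Sebaceous and lipid synthesis genes were higher for 16 of 31, and for 17 adjusted over the list alone (list adjusted p = 2.2e-06). Core histone genes were higher for 20 of 25, and for 22 adjusted over the list alone (list adjusted p = 1.2e-12).

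Matrix proteases were higher for 11 of 22 members, and for 12 adjusted over the list alone (list adjusted p = 0.00011), among them the gelatinase Mmp9 at 4.60 ± 1.04 (adjusted p = 0.00037) and Mmp13 at 4.57 ± 1.17 (adjusted p = 0.0019) in the authors' deposited table. Alarmin genes of neutrophils and keratinocytes were higher, S100a8 by 4.69 ± 1.39 (adjusted p = 0.0085) and S100a9 by 4.62 ± 1.23 (adjusted p = 0.0029), in the authors' deposited table. WNT target genes were lower for 8 of 17, and for 10 adjusted over the list alone, with none higher (list adjusted p = 1.1e-05). Among them the feedback gene Axin2 stood at -1.90 ± 0.35 (adjusted p = 9.4e-06) and the ligand gene Bmp4 at -3.15 ± 0.58 (adjusted p = 8.8e-06) in the authors' deposited table. Cornified envelope genes split, with 8 of 37 higher and 6 lower, and 9 higher and 6 lower adjusted over the list alone (list adjusted p = 0.71). Rptn at 3.67 ± 0.44 (adjusted p = 1.7e-13) and Lce3c at 5.19 ± 1.27 (adjusted p = 0.0011) were higher, and Flg2 at -2.92 ± 0.58 (adjusted p = 3.6e-05) and Lce1m at -2.73 ± 0.63 (adjusted p = 0.00047) lower, in the authors' deposited table. Lce1m was not typical of its family. Lce1h at -0.04 (adjusted p = 0.95), Lce1g at 0.15 (adjusted p = 0.8) and Lce1a1 at -0.61 (adjusted p = 0.19) did not pass in that deposited table. The hair list had a median of -2.38 (list adjusted p = 1.3e-05), with 7 of 38 lower and 1 higher over all genes and adjusted over the list alone. Endothelial genes had a median of 2.23 (list adjusted p = 0.00071, and 0.064 as the adjusted p with a correlation of 0.1), with 6 of 22 higher, and 7 adjusted over the list alone. Red blood cell genes, a list written after the tables were seen, had a median of 3.16 (list adjusted p = 0.041, and 0.076 as the adjusted p with a correlation of 0.05), with 1 of 6 higher over all genes and adjusted over the list alone. The skeletal muscle list had a median of 1.87 (list adjusted p = 0.015, and 0.098 as the adjusted p with a correlation of 0.05), with 0 of 29 changed over all genes and 0 adjusted over the list alone. Of 39 lists 20 were called, 17 with a correlation of 0.05 and 12 with 0.1. With the null spread taken from the genes, which treats a central SD of 1.92 as chance, 11 genes remained called. Centring on the median gave 1342 higher and 1490 lower.

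**Figure D1:**
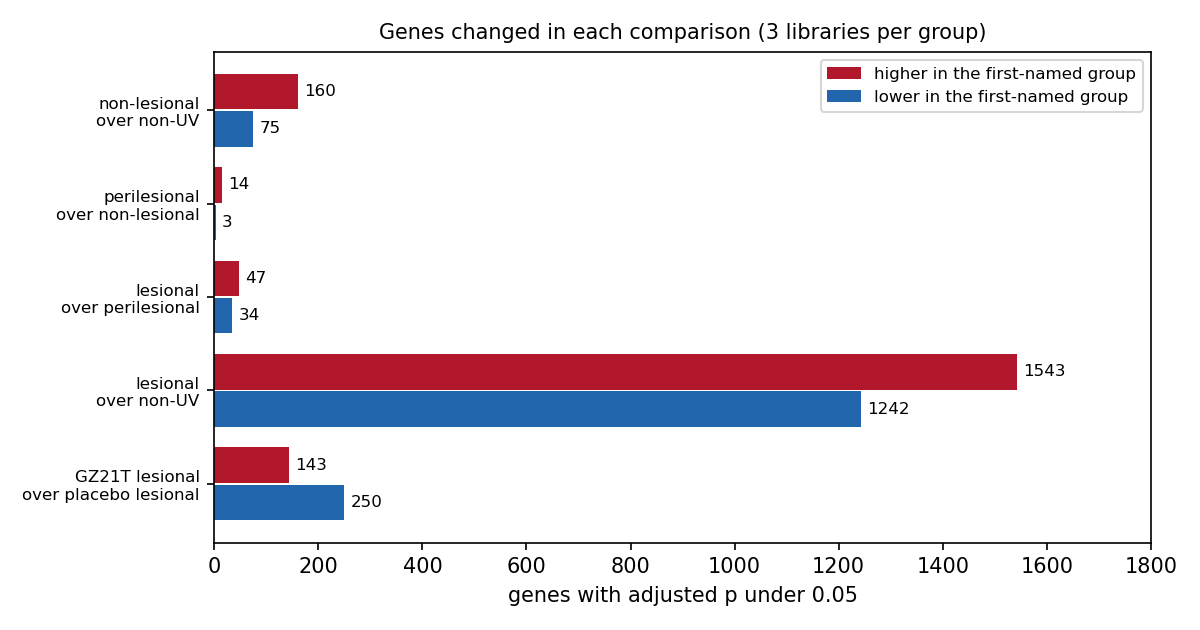
Number of genes with an adjusted p under 0.05 in each of 5 comparisons, with 3 libraries per group. Red bars count genes higher and blue bars genes lower in the group named first, from 14 and 3 in perilesional over non-lesional skin to 1543 and 1242 in lesional over non-UV-exposed skin.

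Lesions treated with GZ21T were compared with lesions under placebo, the comparison that asks what the cream changes. Cornified envelope genes rose as a list under GZ21T, and the lists of proliferation, ribosomal protein, histone and glycolysis genes fell. The list of chemokines and cytokines fell too, on few testable members. With the sign of the authors' deposited table turned to read GZ21T over placebo, 393 of 10899 genes changed, 143 higher and 250 lower, with a median absolute log2 fold change of 0.98 among them. Of 32 cornified envelope genes 16 were higher, and 25 higher and 1 lower adjusted over the list alone (list adjusted p = 7.1e-19). In the other comparisons 37 members were tested. Those left out here include Lce3c, Lce3e and Lce3f, at 1.8, 1.05 and 0.91 in the authors' deposited placebo over GZ21T lesions. These Lce3 genes were thus lower under GZ21T, without a test, so the rise does not cover the whole list. In the authors' deposited table Lce1h was 1.58 ± 0.33 higher (SE; adjusted p = 0.0027), Lce1c 1.65 ± 0.37 higher (adjusted p = 0.0057) and loricrin, Lor, the main protein of the envelope, 1.76 ± 0.49 higher (adjusted p = 0.026). Lor lies at chromosome 3, 92080271 to 92083142, minus strand, and Lce1h at chromosome 3, 92763215 to 92765065, minus strand, of GRCm38. Krt10 of differentiating keratinocytes stood at 1.27 ± 0.57 (adjusted p = 0.15), Krt14 of basal ones at -0.25 ± 0.35 (adjusted p = 0.71) and Krt16 at 0.03 ± 0.45 (adjusted p = 0.98) in the authors' deposited table. The basal keratinocyte list did not pass, with a median of -0.15 over 15 members (list adjusted p = 0.99). The stress keratin and alarmin list was called lower, with a median of -0.87 over 16 members (list adjusted p = 0.038). Its adjusted p was 0.12 with a correlation of 0.05, and 0 members changed over all genes or adjusted over the list alone. Among the genes most raised in the authors' deposited table were Zfyve28 at 2.16 ± 0.48 (adjusted p = 0.0046), Serpina12, the adipokine vaspin, at 1.84 ± 0.38 (adjusted p = 0.0024) and Hs3st6, a heparan sulphate sulphotransferase gene, at 1.95 ± 0.50 (adjusted p = 0.016).

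Of 32 cell cycle genes 5 were lower under GZ21T, and 28 adjusted over the list alone, with none higher (list adjusted p = 9.2e-13). Birc5 in the authors' deposited table stood at -1.31 ± 0.38 (adjusted p = 0.03), the spindle motor Kif11 at -1.02 ± 0.32 (adjusted p = 0.044) and Mki67 at -0.37 ± 0.29 (adjusted p = 0.44). DNA replication genes were lower for 1 of 25 members and for 13 adjusted over the list alone (list adjusted p = 2e-07). The member that passed over all genes was the ribonucleotide reductase subunit Rrm1 at -0.90 ± 0.26 (adjusted p = 0.029) in the authors' deposited table, which was not the largest fall. Core histones were lower for 8 of 24, and for 18 adjusted over the list alone (list adjusted p = 2e-10), and ribosomal proteins for 5 of 41, and for 25 adjusted over the list alone (list adjusted p = 1.7e-12), with none higher in either list. Glycolysis and hypoxia genes were lower for 4 of 22, and for 8 adjusted over the list alone (list adjusted p = 1.6e-06), with Egln3 at -2.17 ± 0.40 (adjusted p = 0.00064) and Ndrg1 at -1.96 ± 0.55 (adjusted p = 0.026) in the authors' deposited table. Of the 35 genes on the chemokine and cytokine list 8 kept an adjusted p. Of these 2 were lower, and 5 adjusted over the list alone (list adjusted p = 0.0018, and 0.24 by Fisher's exact test). The 2 were the cytokine gene Tslp at -3.95 ± 0.89 (adjusted p = 0.0055) and the cyclooxygenase gene Ptgs2 at -3.53 ± 1.00 (adjusted p = 0.029) in the authors' deposited table. ERK feedback and immediate early genes were lower for 3 of 26, and 8 lower and 1 higher adjusted over the list alone (list adjusted p = 0.005, and 0.051 as the adjusted p with a correlation of 0.05). They were Ier3 at -2.03 ± 0.48 (adjusted p = 0.0081), Fosl1 at -2.46 ± 0.75 (adjusted p = 0.041) and Fosb at -3.0 ± 0.93 (adjusted p = 0.042) in the authors' deposited table.

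Interferon genes did not pass under GZ21T, with a median of -0.05 over 29 members (list adjusted p = 0.82), nor did p53 targets (list adjusted p = 0.89) or autophagy genes (list adjusted p = 0.45). Neutrophil genes had a median of -1.97 over 5 members (list adjusted p = 0.59), and S100a8 stood at -3.19 ± 1.37 (adjusted p = 0.14) in the authors' deposited table. The hair list had a median of 1.67 (list adjusted p = 0.005, and 0.12 as the adjusted p with a correlation of 0.1), while its changed member, the desmosomal Dsc2, was lower at -2.08 ± 0.55 (adjusted p = 0.018) in the authors' deposited table, 1 lower of 17 over all genes and adjusted over the list alone. Haemoglobin genes, a sign of blood in the sample, were lower under GZ21T, Hbb-b1 at -5.65 ± 1.6 (adjusted p = 0.028) and Hba-a1 at -5.33 ± 1.45 (adjusted p = 0.023) in the authors' deposited table. Of 36 lists 14 were called, 8 with a correlation of 0.05 and 7 with 0.1. With the null spread taken from the genes, which treats a central SD of 1.64 as chance, 0 genes remained called, with 297 at an unadjusted p under 0.05 against 2498 by the authors' DESeq2 Wald test. Adjusting over every gene with a p-value gave 209 genes, and centring on the median gave 201 higher and 142 lower.

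**Figure D2:**
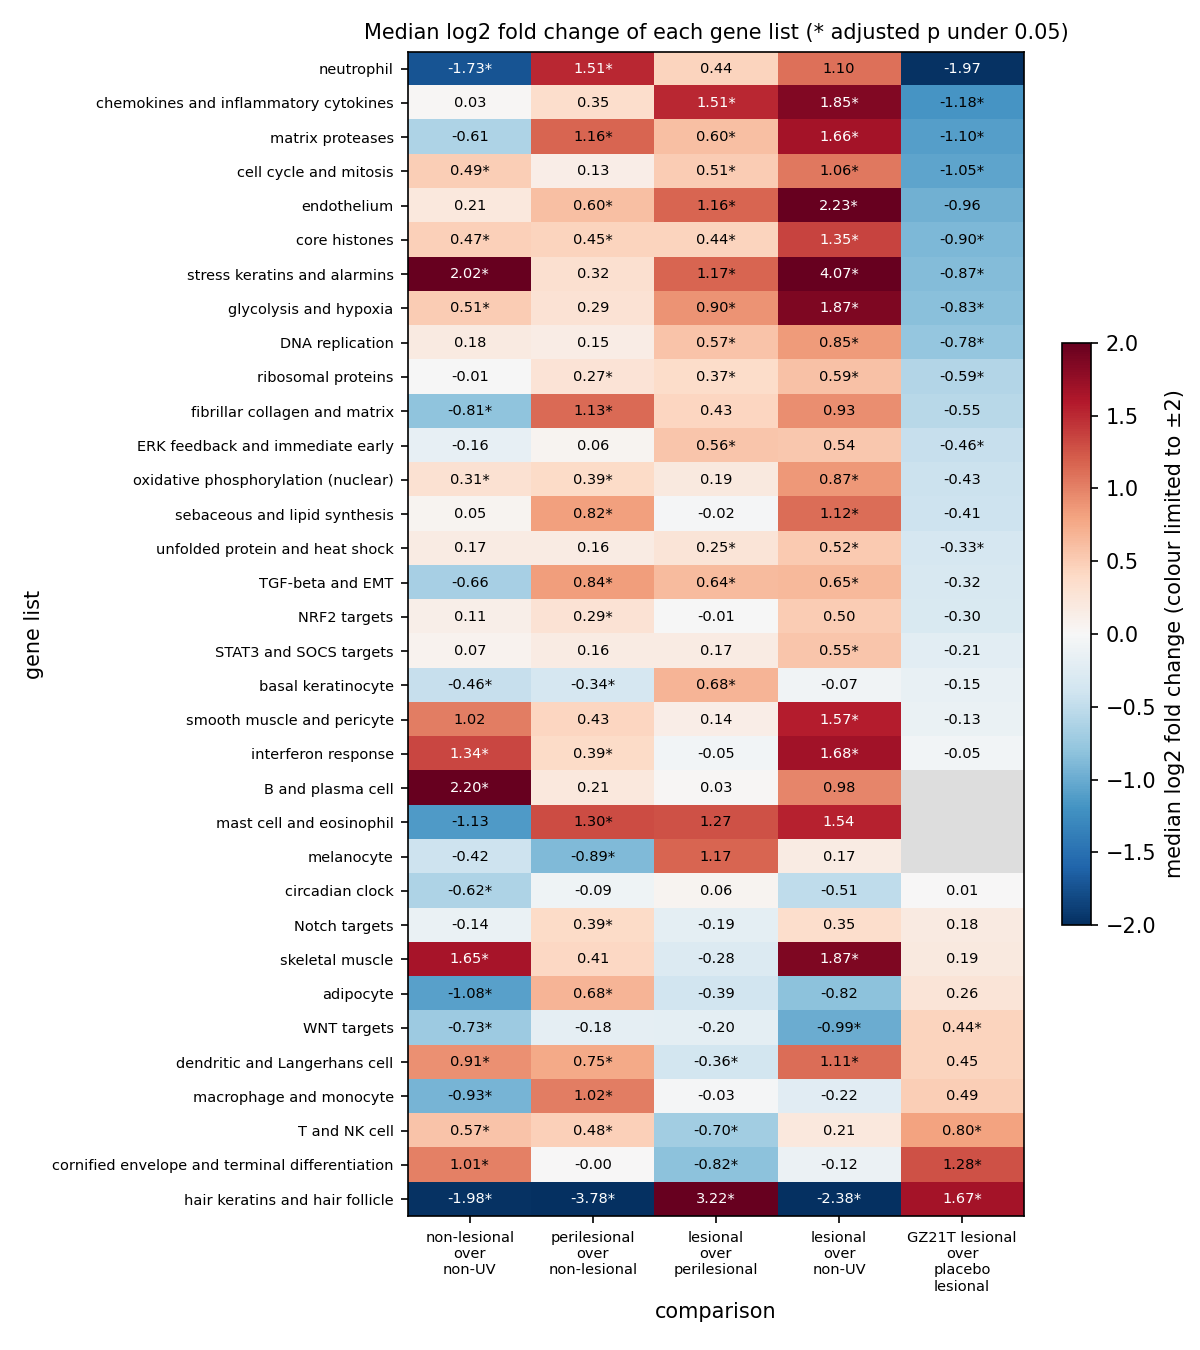
Median log2 fold change of the members of 34 gene lists, those called in at least 1 of 5 comparisons, with the comparison on the horizontal axis and the list on the vertical axis. An asterisk marks an adjusted p under 0.05 in the list test, grey marks lists with too few tested members, and cornified envelope genes read 1.01, 0.00, -0.82, -0.12 and 1.28 from left to right.

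Genes that separate lesions from the skin around them were set against the change under GZ21T. Of the 38 genes higher in lesions and testable in both comparisons, 20 were lower under GZ21T, where independent lists would share 0.87. Of the 32 lower in lesions, 20 were higher under GZ21T, where independent lists would share 0.42, and 0 genes moved the same way in both. Independence is not the value for no effect here, since error of the placebo lesional libraries enters both comparisons with opposite sign. The largest opposite changes were those of Ptgs2, Tslp, Slit1, Fosl1, the hyaluronan synthase Has3, the matricellular Cyr61, the EGF receptor ligand Epgn and the protocadherin Pcdh18. Slit1 rose by 2.94 ± 0.75 in lesions (adjusted p = 0.03) and stood at -3.52 ± 0.77 under GZ21T (adjusted p = 0.0036) in the authors' deposited table. Epgn rose by 2.07 ± 0.47 in lesions (adjusted p = 0.0058) and stood at -2.37 ± 0.48 under GZ21T (adjusted p = 0.0014) in the authors' deposited table. Across 10898 genes, which are not independent replicates, Pearson's r was -0.67 and Spearman's rho -0.71. Both comparisons use the placebo lesional libraries, and unchanged groups simulated with that sharing gave r with outer percentiles of -0.53 and -0.47 over 100 runs. They shared 0 called genes, but groups without any effect are expected to give few calls to share, so that count is a weak comparison for the 40 observed. The covariance was -0.165 beside a simulated -0.084. The libraries are too few to split, so part of the excess may come from the shared controls. When the simulation shared a larger part of each variance, the lower percentile of its r was -0.69, and the observed r no longer lay beyond it.

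**Figure D3:**
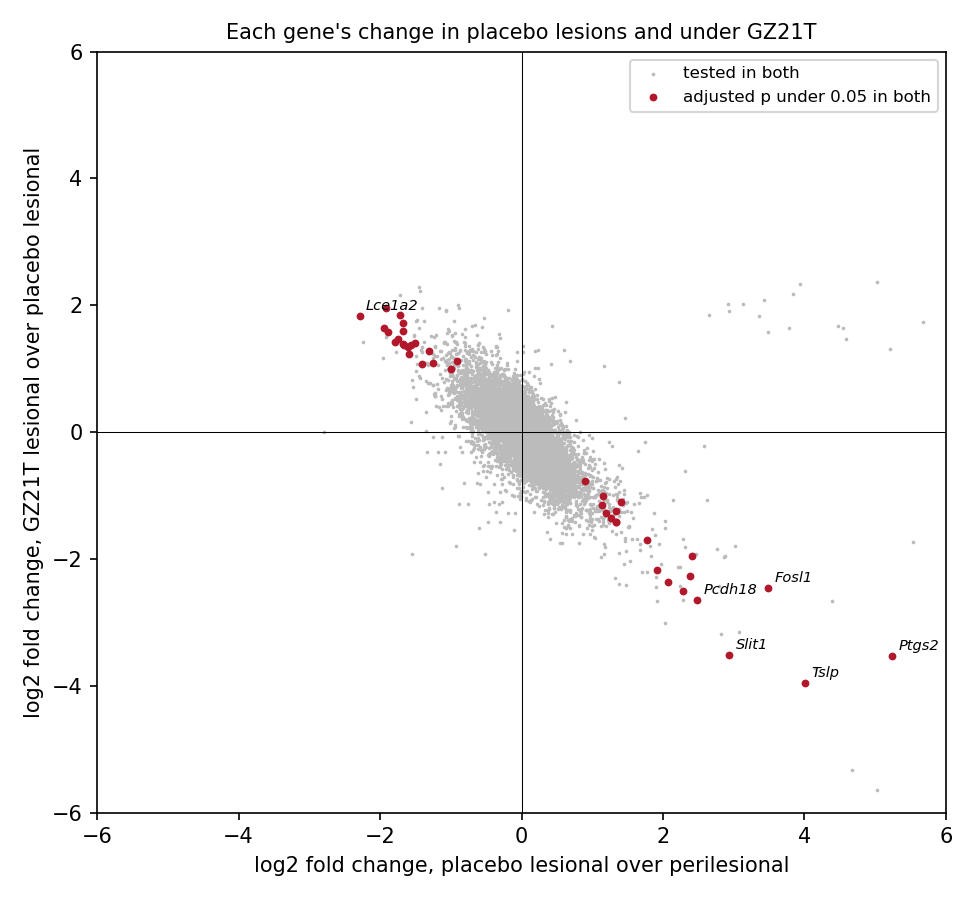
Log2 fold change of 10898 genes in placebo lesional over perilesional skin (horizontal) and in GZ21T lesional over placebo lesional skin (vertical), 1 point per gene. The 40 genes with an adjusted p under 0.05 in both, in red, lie in the quadrants of opposite sign, and a negative slope arises in part because both axes use the placebo lesional libraries.

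Successive steps in placebo skin were compared for the genes called in each. Non-lesional over non-UV skin and perilesional over non-lesional skin shared 0 called genes, and perilesional over non-lesional and lesional over perilesional skin shared 0 as well. Independence gives at most 0.16 in any direction for the former pair and 0.04 for the latter. With 17 called genes in the middle step, these counts cannot show whether the steps change different genes. Between the first and the last step, which have no library in common, 6 genes were higher and then lower where independence gives 0.39, 2 were higher in both where it gives 0.53, and 1 was lower in both where it gives 0.18. Among list members Lce1h is such a gene, at 1.55 ± 0.34 in non-lesional over non-UV skin in the authors' deposited table and at -1.89 ± 0.33 in lesional over perilesional skin. Lce1e, Lce1f and Lce1g of the same cluster were also called higher in the first step. The 6 may thus include several genes of 1 cluster, which independence does not allow for. Across 14124 genes the first and second steps had r = -0.06 and rho = 0.04 with a covariance of -0.027, beside a simulated r of -0.50 and covariance of -0.161. The second and last steps had r = -0.26 and rho = -0.10 with a covariance of -0.127, beside a simulated r of -0.50 and covariance of -0.220. On the genes with an adjusted p in every table the second and last steps had r = -0.13 with a covariance of -0.028, and on the Wald statistic r = -0.10. The first and second steps turned to r = 0.09 and 0.05 in the same settings. The first and last steps had r = -0.06 and rho = 0.04 over 14121 genes, beside simulated values between -0.03 and 0.05, and r = 0.01 on the Wald statistic, within its simulated range.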

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

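No paired analysis was possible because the tables hold no values per library, although the labels give every group the numbers 1 to 3. For the same reason leaving out a library, a block by number, another tool, filters on the mean count and other splits of the libraries could not be run, and precision beyond the deposited SEs is limited by an unknown depth. The genes with an adjusted p in every table, the largest of 3 SEs, transcript length, the removal of fitted changes over 15 and every alternative for lesional over non-UV skin were chosen after seeing the data. No gene list fixed beforehand was called in the opposite direction under any of the 7 list alternatives. Without a call, the neutrophil list in non-lesional over non-UV skin turned from lower to higher on the genes with an adjusted p in every table, and some lists turned by Fisher's exact test, such as hair in GZ21T over placebo lesions. Of named genes, 0 of 284 calls were lost and 8 gained on the genes with an adjusted p in every table, and 27 of 311 were lost and 0 gained when adjusting over every gene with a p-value.

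Genes changed under an adjusted p of 0.01 numbered 110 in non-lesional over non-UV skin, 2 in perilesional over non-lesional, 29 in lesional over perilesional, 1384 in lesional over non-UV and 38 in GZ21T over placebo lesions. Under 0.1 they numbered 30 in perilesional over non-lesional skin, 152 in lesional over perilesional skin and 1092 in GZ21T over placebo lesions. A change of at least 2-fold left 1502 in lesional over non-UV skin and 189 in GZ21T over placebo lesions. Adjusting over every gene with a p-value gave 209 in GZ21T over placebo lesions. A null spread estimated from the genes gave 139, 1, 21, 11 and 0 in the order above, with SDs of 1.09, 1.07, 1.16, 1.92 and 1.64. This construction counts a broad shift of many genes as chance. The largest of 3 SEs gave 53 in lesional over perilesional skin. Over the 4 planned comparisons 70 lists were called, 37 with a correlation of 0.1 and 15 by Fisher's exact test.

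The correlation of -0.67 between lesions and GZ21T no longer lay beyond the simulation with a larger shared part of the variance, which gave -0.67 itself. The added one of lesional over non-UV skin with GZ21T, at -0.58, then lay on the other side of its simulation, at -0.67 and between -0.70 and -0.63. Without Hba-a2, the 1 gene with a fitted change over 15, r was -0.65, and on the Wald statistic r was -0.72. The simulation with the larger shared part was not run without Hba-a2, so whether that gene alone carries this is not settled. The one between the first and last steps in placebo skin fell within its simulation at -0.01 on the genes with an adjusted p in every table, 0.01 on the Wald statistic and -0.03 without muscle, fat and hair lists. The added one of non-lesional over non-UV skin with GZ21T, 0.15, turned to -0.14 on the Wald statistic, -0.09 without the length trend and -0.10 without fitted changes over 15, and Hba-a2 alone sets its sign.

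Adjusted p of gene lists that lost or gained a call follow, by alternative. Other than through fewer genes or a stricter test by construction, the cause was not tested. With a preset correlation of 0.05, calls were lost in non-lesional over non-UV skin at adjusted p of adipocyte 0.087, basal keratinocyte 0.062 and oxidative phosphorylation 0.087. Those lost in perilesional over non-lesional skin had adipocyte 0.13, endothelium 0.15, melanocyte 0.1 and Notch 0.083. For lesional over perilesional skin the values were endothelium 0.051 and unfolded protein 0.13. Lost in lesional over non-UV skin were skeletal muscle 0.098, smooth muscle 0.098 and STAT3 0.069. In GZ21T over placebo lesions those lost had ERK feedback 0.051, matrix proteases 0.11, stress keratin 0.12, T and NK cell 0.083, unfolded protein 0.14 and WNT 0.093. With a correlation of 0.1, calls were lost in non-lesional over non-UV skin at adjusted p of adipocyte 0.2, B cell 0.06, basal keratinocyte 0.15, clock 0.12, collagen 0.14, hypoxia 0.1, neutrophil 0.12, oxidative phosphorylation 0.23 and T and NK cell 0.12. Those lost in perilesional over non-lesional skin had adipocyte 0.26, basal keratinocyte 0.12, endothelium 0.29, interferon 0.11, melanocyte 0.19, Notch 0.16, NRF2 0.12, oxidative phosphorylation 0.13, ribosomal 0.08, T and NK cell 0.12 and TGF-beta 0.061. For lesional over perilesional skin the values were histone 0.08, dendritic cell 0.14, endothelium 0.15, ERK feedback 0.12, matrix proteases 0.065 and unfolded protein 0.27. Lost in lesional over non-UV skin were chemokine 0.064, dendritic cell 0.064, endothelium 0.064, skeletal muscle 0.23, smooth muscle 0.2, STAT3 0.17, TGF-beta 0.066 and unfolded protein 0.095. In GZ21T over placebo lesions those lost had ERK feedback 0.16, hair 0.12, matrix proteases 0.23, stress keratin 0.24, T and NK cell 0.13, unfolded protein 0.29 and WNT 0.18. On ranks, calls were lost in non-lesional over non-UV skin at adjusted p of T and NK cell 0.052. Those lost in perilesional over non-lesional skin had melanocyte 0.075. Gained in non-lesional over non-UV skin were DNA replication 0.0098, mast cell 0.035, matrix proteases 0.045, TGF-beta 0.044 and unfolded protein 0.036. Calls were gained in perilesional over non-lesional skin at DNA replication 0.044. Gained in lesional over perilesional skin were adipocyte 0.034 and mast cell 0.043. Calls were gained in GZ21T over placebo lesions at dendritic cell 0.032, oxidative phosphorylation 0.032 and sebaceous 0.028. Without members of several lists, calls were lost in lesional over non-UV skin at adjusted p of smooth muscle 0.072. For GZ21T over placebo lesions the values were matrix proteases 0.065 and stress keratin 0.12. Gained in non-lesional over non-UV skin were ERK feedback 0.036. On the genes with an adjusted p in every table, calls were lost in non-lesional over non-UV skin at adjusted p of adipocyte 0.51, neutrophil 0.43 and T and NK cell 0.12. Lost in perilesional over non-lesional skin were adipocyte 0.15, endothelium 0.1, neutrophil 0.99, Notch 0.22 and T and NK cell 0.099. In lesional over perilesional skin those lost had endothelium 0.13. Those lost in lesional over non-UV skin had smooth muscle 0.1. For GZ21T over placebo lesions the values were T and NK cell 0.052. With the trend on transcript length removed, calls were lost in non-lesional over non-UV skin at adjusted p of oxidative phosphorylation 0.066. Lost in perilesional over non-lesional skin were melanocyte 0.057 and ribosomal 0.11. In lesional over perilesional skin those lost had unfolded protein 0.054. Those lost in GZ21T over placebo lesions had stress keratin 0.1, unfolded protein 0.085 and WNT 0.084. Calls were gained in non-lesional over non-UV skin at mast cell 0.048. Gained in lesional over perilesional skin were collagen 0.043. Calls were gained in lesional over non-UV skin at collagen 0.036. Gained in GZ21T over placebo lesions were dendritic cell 0.035 and sebaceous 0.021. By Fisher's exact test of called members, calls were lost in non-lesional over non-UV skin at adjusted p of basal keratinocyte 0.96, clock 0.96 and neutrophil 0.86, and adipocyte, B cell, cell cycle, histone, dendritic cell, collagen, hypoxia, hair, oxidative phosphorylation, skeletal muscle and WNT 1 each. For perilesional over non-lesional skin the values were hair 0.14, and adipocyte, basal keratinocyte, histone, dendritic cell, endothelium, collagen, interferon, macrophage, mast cell, matrix proteases, melanocyte, neutrophil, Notch, NRF2, oxidative phosphorylation, ribosomal, T and NK cell and TGF-beta 1 each. Lost in lesional over perilesional skin were ERK feedback 0.96 and TGF-beta 0.96, and basal keratinocyte, cell cycle, histone, dendritic cell, DNA replication, endothelium, hair, ribosomal, stress keratin, T and NK cell and unfolded protein 1 each. In lesional over non-UV skin those lost had chemokine 0.066, dendritic cell 0.066, endothelium 0.089, hair 0.13, STAT3 0.14, TGF-beta 0.077 and unfolded protein 0.066, and oxidative phosphorylation, skeletal muscle and smooth muscle 1 each. Those lost in GZ21T over placebo lesions had chemokine 0.24 and ERK feedback 0.34, and DNA replication, hair, matrix proteases, stress keratin, T and NK cell, unfolded protein and WNT 1 each. Calls were gained in lesional over non-UV skin at ERK feedback 0.0039.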

Other observations

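The 8 lists in the next paragraphs, the contrast of GZ21T lesions with non-lesional skin, and the tests weighed at the end were chosen only after the result was seen, except that the removal of the length trend from the correlation was chosen after the tables, but before its own value, were seen. Skint genes encode butyrophilin-like proteins of keratinocytes, the first of which selects epidermal gamma-delta T cells. Of 11 Skint genes 9 were lower in lesional than in non-UV skin, and 10 adjusted over the list alone (list adjusted p = 1.3e-11). In the authors' deposited table Skint7, at chromosome 4, 111972923 to 111988223, plus strand, of GRCm38, stood at -4.95 ± 0.62 (adjusted p = 2.1e-12) and Skint6 at -3.96 ± 0.60 (adjusted p = 1.8e-08). Under GZ21T 1 of 10 was higher, Skint3 at 1.06 ± 0.32 (adjusted p = 0.041) in the authors' deposited table, and 3 were higher adjusted over the list alone (list adjusted p = 2.3e-05). The Lce1 genes form a cluster on chromosome 3 of GRCm38, from Lce1a1, which starts at 92646535, to Lce1m, which ends at 93019060. Of 14 such genes 11 were lower in lesional than in perilesional skin, and 14 adjusted over the list alone (list adjusted p = 1.7e-41), and 11 were higher under GZ21T, and 14 adjusted over the list alone (list adjusted p = 9.8e-19). In non-lesional over non-UV skin 4 of them were higher, and 11 adjusted over the list alone (list adjusted p = 2.6e-15). With a preset correlation of 0.1 the list adjusted p was 1.5e-20 in lesional over perilesional skin. Under GZ21T it was then 2.2e-09, and in non-lesional over non-UV skin 9.4e-08. The correlation among these neighbouring genes of 1 cluster could not be estimated and may be higher. The counts and list p may thus take 1 signal as several.

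Cholesterol synthesis genes were higher for 15 of 20 members in lesional over non-UV skin, over all genes and adjusted over the list alone (list adjusted p = 3.2e-11), with Idi1 at 1.99 ± 0.30 (adjusted p = 8.1e-09) in the authors' deposited table. Genes of lysosomes and lipid-laden macrophages were lower for 8 of 20 and higher for 1 in non-lesional over non-UV skin, and 12 lower and 1 higher adjusted over the list alone (list adjusted p = 1.8e-13). In perilesional over non-lesional skin 0 of the 20 changed over all genes, and 7 were higher adjusted over the list alone (list adjusted p = 2e-14). The non-lesional libraries enter both comparisons with opposite sign, so the fall and the rise are not separate findings. Hox genes, which mark body position, differed from non-UV skin already in non-lesional skin, where Hoxb7 stood at 2.73 ± 0.55 (adjusted p = 0.00021) in the authors' deposited table and the HoxA and HoxB list had an adjusted p of 9.6e-08, or 0.00051 with a correlation of 0.1. Whether non-UV skin came from another body site was not tested. In lesional over non-UV skin HoxA and HoxB genes were higher for 4 of 17, over all genes and adjusted over the list alone (list adjusted p = 0.041, and 0.11 as the adjusted p with a correlation of 0.05), with Hoxb7 at 2.38 ± 0.55 (adjusted p = 0.00049) in the authors' deposited table. HoxC genes were lower for 4 of 7, and 5 adjusted over the list alone (list adjusted p = 0.0039), with Hoxc4 at -2.40 ± 0.47 (adjusted p = 3.4e-05) in the authors' deposited table. Red blood cell genes were lower for 3 of 3 under GZ21T, over all genes and adjusted over the list alone (list adjusted p = 3.5e-05), and in placebo lesional over perilesional skin 5 of 5 were higher adjusted over the list alone, with 0 over all genes (list adjusted p = 2.1e-05, and 0.00038 with a correlation of 0.1). Hbb-b2 and Hbb-bt among those 5 carry identical values and amount to 1 measurement. Hba-a2 is 1 of the 3 under GZ21T, although a group without reads sets its fitted value, and that count and list p include it. Over non-lesional skin the list's median was 5.31 in placebo lesions and -0.32 in GZ21T lesions. EGF family genes were lower for 1 of 8 under GZ21T, and 3 adjusted over the list alone (list adjusted p = 0.026, and 0.053 as the adjusted p with a correlation of 0.05). In lesional over perilesional skin the EGF family ligands Btc and Epgn changed in opposite directions, at -2.25 ± 0.48 (adjusted p = 0.003) and 2.07 ± 0.47 (adjusted p = 0.0058).

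GZ21T lesions were also set against placebo non-lesional skin by a derived contrast with a normal Wald test. Of 15187 genes 0 changed, 503 had an unadjusted p under 0.05, and the smallest adjusted p was 0.16. Placebo lesions against the same skin, with the largest of 3 deposited SEs, gave 635 changed genes, 353 higher and 282 lower, and GZ21T lesions with that SE gave 0, with 462 at an unadjusted p under 0.05. The difference between these contrasts is GZ21T over placebo lesions, in which 393 genes changed. The SD of log2 fold changes over genes was 0.35 for GZ21T lesions and 0.61 for placebo lesions. Cornified envelope genes had medians of -0.05 in GZ21T lesions and -1.19 in placebo lesions, cell cycle genes -0.36 and 0.63, glycolysis and hypoxia genes 0.29 and 1.25, and ribosomal protein genes 0.01 and 0.63. Macrophage genes, at 1.08 and 1.07, and mast cell genes, at 2.53 and 2.27, had medians close to each other. A count of 0 does not show that GZ21T lesions equal non-lesional skin.

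The first pattern weighed is the table whose name and header differ. If it held lesional over perilesional skin, genes without reads in perilesional and non-lesional skin could not be negative in it, yet 271 are. If it held lesional over non-UV skin, genes without reads in non-UV and non-lesional skin could not be negative, and 0 are. The header is thus in line with the values, and the name is not. Whether back skin is the non-UV-exposed group rests on elimination and was not tested.

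The second pattern is the opposite sign of changes in lesions and under GZ21T. A trend with transcript length is argued against, since r was -0.66 after its removal from both, below the lower percentile of the simulated values, -0.54. Chance error of the placebo lesional libraries, which both comparisons use, cannot be told apart from an effect of GZ21T by the covariance: it was 1.96 times the simulated one, and errors that many genes share could reach 5.02 times. Perilesional over non-lesional skin shares no library with GZ21T over placebo lesions and still had r = -0.36 and rho = -0.43, beside simulated values between -0.04 and 0.05, which leave out errors that genes share and any mouse common to the placebo sites. An effect of GZ21T, which the design names, stays open as a hypothesis, as does unlike sampling of the lesions, blood content included.

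The third pattern is the higher level of cornified envelope genes in GZ21T lesions. A larger share of epidermis may raise all keratinocyte genes, but the upper quartile of basal keratinocyte genes was 0.06, under the lower quartile of 0.74 of the cornified envelope genes. A trend with transcript length is argued against by an adjusted p of 1.4e-23 for the list after its removal. A thicker outer epidermis and a change in differentiation within the same cells were not distinguished by these tests. The pattern remains a hypothesis about GZ21T, found and tested on the same data.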
